A study of Homo sapiens with 6 samples.

How the data were processed

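RNA from SU-DHL-8 cells, a human diffuse large B-cell lymphoma line, was sequenced after 24 h with 15 µM beta-sitosterol, a plant sterol, or with the solvent DMSO. There were 3 libraries per group, 6 in all. The labels describe replicate experiments, and the p-values of single genes given here measure only the spread between these samples. Those of the gene list test at a preset correlation compare listed genes with other genes, and rest largely on the spread between genes. Per the labels' protocols, total RNA was extracted with TRIzol and libraries followed a standard Illumina procedure; whether polyadenylated RNA was selected and whether the libraries kept strand are not given in the sources used here.

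The deposited count table holds whole read counts per gene, not normalized, and the deposited TPM table holds the same genes scaled for length and library by the authors. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10, featureCounts 2.0.1 and StringTie 2.2.1, with the human GRCh38 build, without saying which step each served. The gene annotation and the handling of multi-mapping reads are not given in the sources used here. Each TPM value equals the gene's count divided by a constant for the gene and a constant for the library, so the TPM table is the same measurement on another scale. The listed TPM summed to 64.6%, 39.5% and 69.2% of a full TPM total in DMSO replicates 1, 2 and 3, and to 57.8%, 57.0% and 57.6% in the treated replicates, so the TPM denominator held more than the listed rows, most of all in DMSO replicate 2.

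The table lists 65807 rows. A repeat of an earlier symbol was dropped in 61 rows, of which 2 held counts, leaving 65746 genes; 47323 of them were at 0 in all 6 libraries. Some of these zeros concern genes that most cells use. Among protein-coding genes matched to GENCODE v29 by identifier, 91.4% of the 625 whose symbol differs from that release were listed at 0 in every library, against 17.6% of the 18521 with an unaltered symbol. Of 752 members of the fixed gene lists found in the table, 74 were listed at 0, among them all 34 replication-dependent histone genes, and none of the 13 mitochondrially encoded genes was matched by name. No statement is made here on the expression of those genes.

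Counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 after TMM scaling and filterByExpr, treatment being the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken as the absolute log2 fold change over the square root of F. Levels are CPM, library-scaled counts from edgeR with TMM factors, as mean ± SD of 3 libraries. Before the data were examined, 35 gene lists, the tests, the naming rule and most alternatives were fixed. Lists with at least 5 tested genes, 29 in number, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it. fry asks whether the genes of a list move on balance in one direction and does not compare them with other genes.

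Genes were named by a rule: the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 8 smallest p-values, up to 3 members of each list past the list test and 1 of each other list, by smallest p, and 12 genes chosen in advance. The rule gave 74 genes, of which some are not reported here. Other list members are named only where few members of a list passed, or as stated, and were chosen after their values were seen. Positions are those of RefSeq on GRCh38.p14, matched by symbol. Of the named genes, 40 overlap another annotated gene on either strand, and since strand use in counting is not stated, reads in such overlaps cannot be assigned with certainty. Counts of ribosomal protein genes, FTL, HLA genes, SNORD3A and the ribosomal DNA gene MIR3648-1 are uncertain for another reason, because near-identical copies or pseudogenes exist.

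The test was checked on simulated counts for the 11525 tested genes with 200 genes changed. It found 72% of the 2-fold and 97% of the 4-fold changes, and 3.98% of its calls were false. Both groups were drawn with the same dispersion per gene. These rates therefore do not cover the unequal spread of the data (median SD 0.27 log2 units in DMSO and 0.09 in treated libraries). In simulated counts with 1 list shifted, the list test called that list and 0 of the others. Genes were drawn independently there, so this does not check the list test where genes of a list vary together. Alternatives were RLE factors or library totals in place of TMM, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) or log2(TPM + 0.1), a replicate block, protein-coding genes alone, a 2-fold minimum, and each library left out. After the data were seen, camera at an estimated correlation was also run with RLE factors, library totals, the 1 CPM filter, log2(TPM + 1), each library left out and the trend removed. A further alternative, also chosen then, removed each library's trend with transcript length and GC content (natural splines with 5 degrees of freedom and an interaction with 3 per term, fitted on values limited to the 2nd and 98th percentiles). Transcript length up to a constant came from the ratio of counts to TPM. It is the length behind the TPM values and need not be that of the mature RNA. GC content came from the longest GENCODE v29 transcript, known for 98.7% of tested genes. On simulated data with a length trend this correction moved the correlation of fold change with length across genes from -0.70 to -0.07. The test made 438 false calls there without the correction and 17 with it. The 3.98% given above is from simulated counts without such a trend. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

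Library totals ran from 26453281 to 35565620 counts. At these depths counting error is small for genes above a few CPM, and the spread between libraries limits precision. Replicates of a group were compared by a chi-square test on genes with at least 20 counts, and no pair agreed within sampling noise: chi-square per degree of freedom was 40.0 to 233 among DMSO libraries and 4.46 to 5.87 among treated ones.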

Results

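The comparison asked how the transcriptome of SU-DHL-8 lymphoma cells differed after 24 h with 15 µM beta-sitosterol from that of cells given DMSO alone. Read counts per gene were available for 3 libraries of each group. Totals were 33536824, 31314446 and 35565620 counts in DMSO replicates 1 to 3 and 29360142, 26453281 and 27839616 in the treated replicates. Treated libraries were closely alike, with correlations of log2 CPM across genes of 0.994, while DMSO libraries ranged from 0.972 to 0.991, DMSO replicate 2 correlating least with the others (0.982 and 0.972). The median SD between replicates was 0.27 log2 units in DMSO and 0.09 in treated cells. Correlations between the groups were lower, from 0.940 to 0.959.

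Genes that rose included the AP-1 transcription factor genes JUN and FOS, which belong to the early response to stimulation. JUN went from 6.65 ± 0.77 to 268 ± 13.3 CPM (SD, n = 3 per group) and FOS from 2.17 ± 0.51 to 66.2 ± 1.46 CPM. The cytokine gene TNF, the kinase gene SGK1 and several short non-coding RNAs rose with them. Among genes that fell, RCSD1 had the smallest p, going from 830 ± 26.9 to 207 ± 2.002 CPM, and AKAP12, a kinase-anchoring protein gene, had the largest fall among called genes with a mean of at least 5 CPM and no overlap between groups. Across the 11525 genes tested with edgeR, 2185 were higher and 2512 lower after beta-sitosterol, 4697 in all. A change of at least 2-fold was reached by 1048 higher and 734 lower genes, and at least 4-fold by 293 higher and 57 lower ones. The 3 treated values lay wholly above or below the 3 DMSO values for 56.1% of tested genes, where chance gives 10%. The share of calls that were higher was 46.5% on TMM-scaled counts and 24.3% on log2(TPM + 1), a scale on which the median of all genes lay at -0.19. Leaving out treated replicate 1, 2 or 3 took the count of calls to 3127, 3094 or 3161, and leaving out DMSO replicate 1, 2 or 3 took it to 3819, 6640 or 5142.

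Among the largest rises, JUN (ENSG00000177606, chromosome 1, 58780791 to 58784047) had a log2 fold change of 5.33 ± 0.15 (SE; edgeR adjusted p = 1.78e-06). FOS (ENSG00000170345, chromosome 14, 75278828 to 75282230) followed at 4.93 ± 0.20 (edgeR adjusted p = 1.36e-05). SGK1 (ENSG00000118515, chromosome 6, 134169256 to 134318112) reached 4.91 ± 0.21 and TNF (ENSG00000232810, chromosome 6, 31575565 to 31578336) reached 4.37 ± 0.20. The small nucleolar RNA gene SNORD3A (ENSG00000263934, chromosome 17, 19188016 to 19188232) went from 0.55 ± 0.29 to 64.0 ± 6.82 CPM. The RNase P RNA gene RPPH1 went from 0.57 ± 0.36 to 11.1 ± 11.4 CPM, 1 treated library lying far above the others. MIR3648-1, within a ribosomal DNA unit, went from 0.07 ± 0.09 to 21.2 ± 6.87 CPM. The pseudogene KLKP1 had 3 counts over the DMSO libraries and 953 over the treated ones, a ratio of 383 with a 95% counting interval of 131 to 1861. Genes with the smallest p-values further held IER3, from 1.02 ± 0.07 to 16.1 ± 0.70 CPM, and FOSB, from 2.72 ± 0.34 to 32.8 ± 2.68 CPM.

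Among the largest falls, AKAP12 (ENSG00000131016, chromosome 6, 151239967 to 151358559) fell by 2.76 ± 0.23 on the log2 scale (SE; edgeR adjusted p = 1.61e-04). BAHCC1 fell from 369 ± 78.6 to 62.1 ± 3.95 CPM. APBB1IP, an adaptor of integrin signalling, fell from 85.4 ± 21.6 to 16.2 ± 0.24 CPM. SIPA1L3, DAB2IP, MAML2, ELFN2 and the steroid sulfatase gene STS had log2 fold changes of -2.39, -2.37, -2.33, -2.28 and -2.24. RCSD1 (ENSG00000198771, chromosome 1, 167630232 to 167708696) had a log2 fold change of -2.0004 ± 0.10 (edgeR adjusted p = 3.80e-05).

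**Figure D1:**
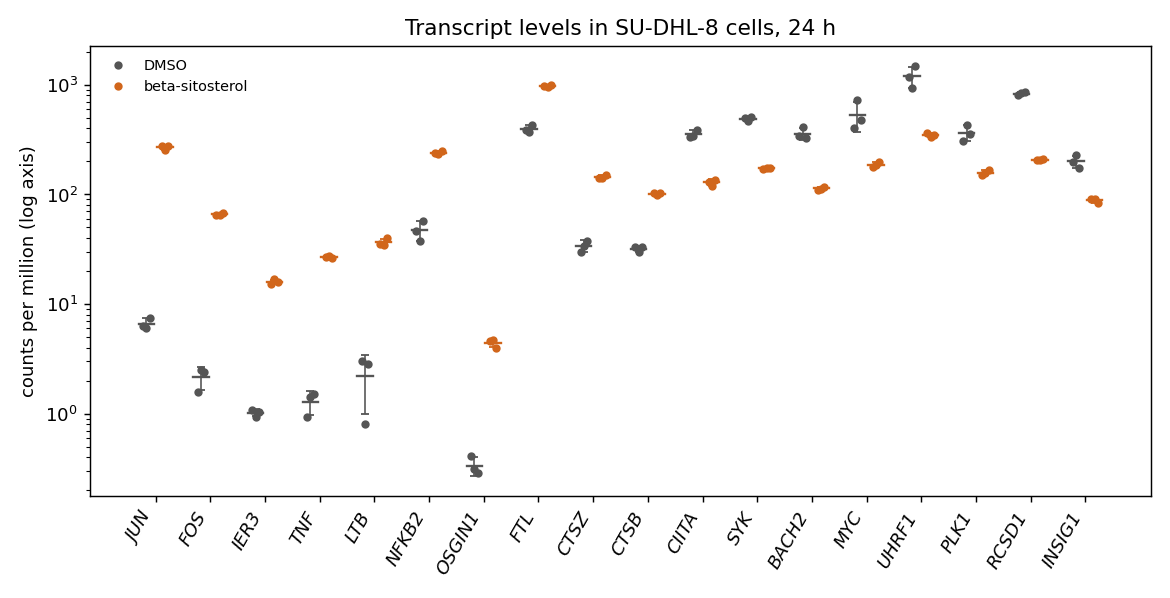
CPM on a log axis for 18 named genes, with each library as a point, the group mean as a line and the SD as a bar (n = 3 per group; DMSO grey, beta-sitosterol orange). JUN lies near 6.65 CPM in DMSO and near 268 in treated cells, and RCSD1 near 830 in DMSO and 207 in treated cells.

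None of the 5 sterol and lipid lists passed the list test with camera at the preset correlation. In fry, which does not compare a list with other genes, adjusted p was 1.79e-04 for fatty acid synthesis, down. It was 0.0039 for other SREBP2 targets, down, and 0.0018 for LXR targets, up. The cholesterol synthesis and sphingolipid lists did not pass fry either (adjusted p = 0.11 and 0.22). Of 20 tested cholesterol synthesis genes 5 fell, FDFT1, HMGCS1, LSS and MVK among them, and ACAT2 rose. The list was not past the list test (camera adjusted p = 0.44; 1 higher and 5 lower adjusted over the list alone). SQLE, an enzyme of the pathway, had a log2 fold change of -0.33 ± 0.13 (edgeR adjusted p = 0.077), which missed the threshold. Without DMSO replicate 3 its adjusted p was 0.036. Among 12 other SREBP2 targets and uptake genes 5 fell and 2, NPC2 and MYLIP, rose (camera adjusted p = 0.48, with the same counts adjusted over the list alone). Among those that fell were the sterol sensor gene INSIG1 from 199.95 ± 25.97 to 88.5 ± 4.79 CPM and the lipoprotein receptor gene SCARB1 from 298 ± 37.1 to 133 ± 0.60 CPM. Of 12 fatty acid synthesis genes 5 fell and 0 rose, ACACA, FASN, SCD, ACLY and SREBF1 (camera adjusted p = 0.068; 5 adjusted over the list alone). ACACA went from 265 ± 0.63 to 115 ± 5.96 CPM. Of 10 LXR targets and export genes 4 rose, APOE, PLTP, MYLIP and ABCG1, and 0 fell (camera adjusted p = 0.20; 4 adjusted over the list alone). The list passed, with an adjusted p of 0.044 (adjusted p = 0.27 with an estimated correlation), when the length and GC trend was removed and DMSO replicate 2 left out, an alternative chosen after seeing the data. APOE went from 1.27 ± 0.52 to 6.74 ± 1.07 CPM. ABCG1 passed narrowly (edgeR adjusted p = 0.045) and missed the threshold without DMSO replicate 1 (0.077) or without treated replicate 1, 2 or 3 (0.094, 0.11 and 0.12). ABCA1, a sterol exporter, stood at 1.23 ± 0.49 and 1.45 ± 0.68 CPM (edgeR adjusted p = 0.67). Sphingolipid and membrane lipid genes split, with 6 higher and 6 lower of 19 (camera adjusted p = 0.97, with the same counts adjusted over the list alone), SPHK2 among the lower. Leaving out a library moved some of these counts by over 1.5 times. Cholesterol synthesis genes were lower in 9 and higher in 2 without DMSO replicate 2, in which the mean log2 CPM of the list lay at -0.27 relative to the DMSO mean, and lower in 6 and higher in 3 without DMSO replicate 3. Without treated replicate 3, 1 of the other SREBP2 targets was higher and 4 lower, and 2 LXR targets were higher and 0 lower. Sphingolipid genes were higher in 2, 2 or 4 and lower in 3, 4 or 3 without treated replicate 1, 2 or 3. With the trend removed, 4 cholesterol synthesis genes were higher and 7 lower, 4 other SREBP2 targets higher and 5 lower, and 1 of 11 fatty acid genes higher and 6 lower.

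Of the 29 lists tested, 9 passed the list test at the preset correlation, and 0 of them did so with an estimated correlation, so each is given with that second p. Immediate early and activation genes were higher in 13 of 23 tested members and lower in 2, MYC and KLF2 (camera adjusted p = 9.37e-04; adjusted p = 0.27 with an estimated correlation, and 13 higher and 5 lower adjusted over the list alone). NF-kB targets were higher in 12 of 21 and lower in 3, IRF4, NFKB1 and TNIP1 (camera adjusted p = 0.0034; adjusted p = 0.26 with an estimated correlation, with the same counts adjusted over the list alone). NFKB2, which encodes a subunit of the factor, went from 47.3 ± 9.65 to 240.2 ± 7.37 CPM. The lymphotoxin gene LTB went from 2.23 ± 1.23 to 36.7 ± 2.83 CPM. NRF2 targets, genes of the oxidative stress response, were higher in 12 of 18 and lower in 1, the export pump gene ABCC1 (camera adjusted p = 0.0028; adjusted p = 0.26 with an estimated correlation, with the same counts adjusted over the list alone). OSGIN1 went from 0.34 ± 0.06 to 4.45 ± 0.39 CPM and FTL, ferritin light chain, from 398 ± 32.6 to 973 ± 24.8 CPM. Lysosome and autophagy genes were higher in 16 of 30 and lower in 3, ULK1, ATP6V0D1 and UVRAG (camera adjusted p = 0.0020; adjusted p = 0.38 with an estimated correlation, with the same counts adjusted over the list alone). The protease genes CTSZ and CTSB rose from 34.0 ± 4.08 to 145 ± 5.05 CPM and from 32.1 ± 1.99 to 101.8 ± 1.81 CPM. The autophagy receptor gene SQSTM1 rose from 54.8 ± 10.2 to 164 ± 4.03 CPM. With the length and GC trend removed, an alternative chosen after seeing the data, 13 immediate early genes were higher and 4 lower.

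Antigen presentation genes were higher in 13 of 22 and lower in 2 (camera adjusted p = 0.0028; adjusted p = 0.38 with an estimated correlation, with the same counts adjusted over the list alone). HLA-DQA1 went from 2.31 ± 0.40 to 9.25 ± 1.48 CPM. The lower members were TAPBP and CIITA, the coactivator of class II genes, which went from 356 ± 29.4 to 129 ± 9.14 CPM. Cytosolic ribosomal protein genes were higher in 22 of 33 and lower in 0 (camera adjusted p = 1.11e-08; adjusted p = 0.45 with an estimated correlation, and 27 higher adjusted over the list alone). RPL35 went from 1002 ± 31.8 to 2938 ± 102 CPM, and RPL27 and RPS27 had log2 fold changes of 1.12 and 1.39. Nuclear genes of the respiratory chain were higher in 18 of 29 and lower in 1, SDHA (camera adjusted p = 6.43e-06; adjusted p = 0.45 with an estimated correlation, and 21 higher and 1 lower adjusted over the list alone). UQCRB went from 73.8 ± 13.5 to 237 ± 14.5 CPM, COX6C from 74.6 ± 8.72 to 189 ± 2.54 CPM and NDUFB8 from 2.195 ± 0.507 to 9.20 ± 0.63 CPM. In DMSO replicate 2 the mean log2 CPM of the ribosomal protein list lay at -0.50 and that of the respiratory list at -0.44 relative to the DMSO mean. Without that library both lists were still called (adjusted p = 4.75e-09 and 1.51e-05; adjusted p = 0.38 with an estimated correlation for each), with 30 higher and 0 lower ribosomal and 22 higher and 3 lower respiratory genes. Leaving out any other library in turn left 0 lower respiratory genes. Lower antigen presentation genes numbered 1 without DMSO replicate 3, without treated replicate 1, 2 or 3, or with the length and GC trend removed.

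**Figure D2:**
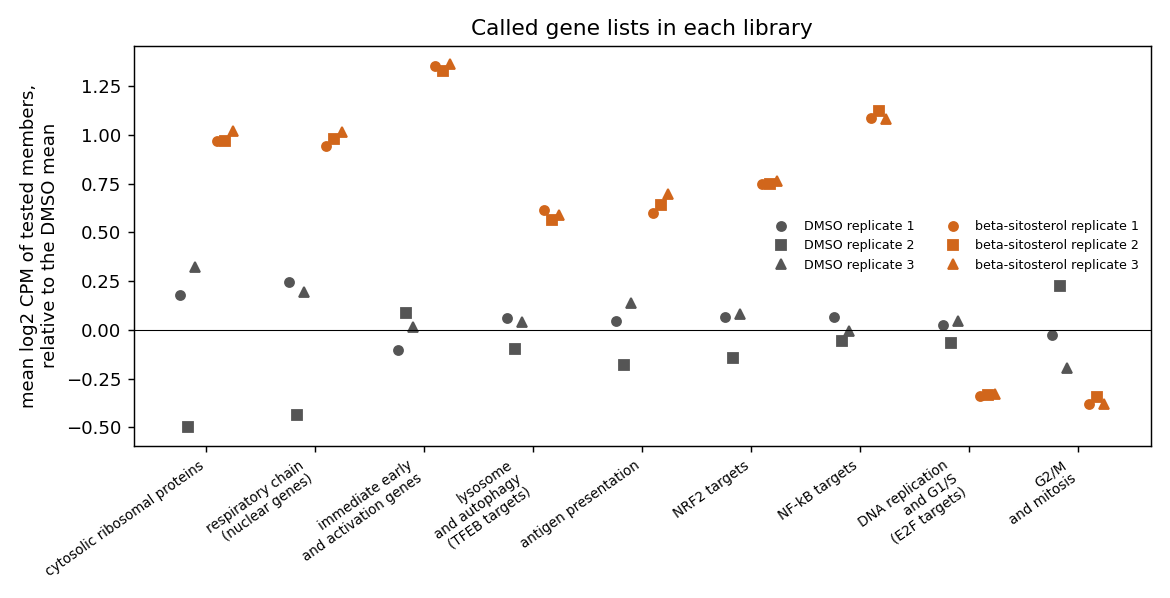
Mean log2 CPM of the tested members of each called list, relative to the mean of the 3 DMSO libraries, with each library as a point (circle, square and triangle for replicates 1, 2 and 3; DMSO grey, beta-sitosterol orange). DMSO replicate 2 lies at -0.50 for ribosomal proteins, and the treated libraries at 0.97, 0.97 and 1.02.

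Proliferation genes fell in part. DNA replication and G1/S genes were lower in 12 of 32 and higher in 0 (camera adjusted p = 0.0061; adjusted p = 0.26 with an estimated correlation, and 12 adjusted over the list alone). UHRF1, which maintains DNA methylation, went from 1198 ± 266 to 351 ± 14.4 CPM, E2F2 from 692 ± 123 to 292 ± 5.50 CPM and the chromatin assembly gene CHAF1A from 237 ± 15.3 to 141 ± 5.62 CPM. G2/M and mitosis genes were lower in 14 of 30 and higher in 3, PTTG1, MAD2L1 and CDC25C (camera adjusted p = 0.013; adjusted p = 0.52 with an estimated correlation, and 3 higher and 15 lower adjusted over the list alone). For that list fry gave an adjusted p of 0.059, against 6.88e-04 for the replication list and 3.70e-04 for the MYC target list below. The mitotic kinase gene PLK1 went from 366 ± 61.2 to 158 ± 9.25 CPM, the kinesin gene KIF20A from 193 ± 35.7 to 109 ± 3.72 CPM. PTTG1 rose from 124 ± 10.96 to 203 ± 9.82 CPM. MKI67, a marker of cycling cells, fell from 1026 ± 458 to 507 ± 18.5 CPM (edgeR adjusted p = 0.016), and missed the threshold without treated replicate 1, 2 or 3 (0.063, 0.052 and 0.054). In DMSO replicate 2 it stood at 1555 CPM, against 764 and 759 in the other DMSO libraries. Without that library its log2 fold change was -0.59, against -1.02 with it. The mean log2 CPM of the G2/M list, relative to the DMSO mean, was 0.22 in DMSO replicate 2 and -0.03 and -0.20 in DMSO replicates 1 and 3, and the list was called without replicate 2 (camera adjusted p = 0.036; adjusted p = 0.56 with an estimated correlation). MYC targets and ribosome biogenesis genes were lower in 10 of 30 and higher in 2, NME1 and FBL (camera adjusted p = 0.095, and 0.033 on log2(TPM + 1), where adjusted p = 0.98 with an estimated correlation, with the same counts adjusted over the list alone). MYC itself went from 535 ± 167 to 187 ± 9.81 CPM (log2 fold change -1.52 ± 0.21, edgeR adjusted p = 8.74e-04), with 724 CPM in DMSO replicate 2 against 407 and 476 in replicates 1 and 3. The RNA polymerase I gene POLR1A went from 259 ± 7.10 to 147 ± 4.87 CPM. Replication genes were lower in 19 and higher in 1 without DMSO replicate 2, and lower in 11 and higher in 1 without DMSO replicate 3. Without treated replicate 1, 2 or 3 the G2/M list had 8, 8 or 7 lower genes and 1 higher. With the length and GC trend removed, chosen after seeing the data, 18 of 31 replication genes were lower and 1 higher, and 13 of 29 MYC list genes lower and 4 higher.

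The lists of B-cell genes did not pass the list test with camera at the preset correlation. In fry, adjusted p was 8.21e-04 for the B cell receptor pathway and 0.0026 for germinal centre genes, both down. It was 0.94 for plasma cell genes. Of 21 tested B cell receptor pathway genes 9 were lower and 2, CR2 and CD79A, higher (camera adjusted p = 0.26, with the same counts adjusted over the list alone). The kinase gene SYK went from 490 ± 23.9 to 173 ± 0.99 CPM. Germinal centre genes were lower in 6 of 17 and higher in 0 (camera adjusted p = 0.26; 6 adjusted over the list alone), and lower in 7 and higher in 4 without DMSO replicate 2. The repressor gene BACH2 went from 359 ± 44.0 to 113 ± 3.92 CPM. BCL6 stood at 4.29 ± 1.44 and 5.91 ± 0.96 CPM (edgeR adjusted p = 0.18) and, without DMSO replicate 2, had an adjusted p of 0.0030. Plasma cell genes split 4 higher and 4 lower of 13 (camera adjusted p = 0.86, with the same counts adjusted over the list alone). SEC11C stood at 34.4 ± 3.98 and 134 ± 8.62 CPM. Plasma cell genes were higher in 2 and lower in 4 without treated replicate 1, 2 or 3. With the length and GC trend removed, chosen after seeing the data, 5 B cell receptor pathway genes were higher and 8 lower, and 1 germinal centre gene was higher and 7 lower.

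The cell death, p53, ATF4, unfolded protein, heat shock, ferroptosis and splicing stress lists were not called at the preset correlation. In fry, adjusted p was 0.0057 for p53, 0.0018 for unfolded protein and 0.0031 for heat shock genes, all up. It was 0.0012 for ferroptosis and 0.0048 for splicing stress genes, both up, and 0.063 and 0.11 for the cell death and ATF4 lists. BCL2 family and cell death genes were higher in 7 of 26 and lower in 1, BCL2L1, the gene of an anti-apoptotic protein (camera adjusted p = 0.20; 6 higher and 1 lower adjusted over the list alone). PMAIP1, which encodes the pro-apoptotic protein NOXA, went from 44.0 ± 4.24 to 147 ± 6.16 CPM. BCL2 stood at 9.89 ± 0.72 and 8.14 ± 1.14 CPM (edgeR adjusted p = 0.19). p53 targets were higher in 4 of 22, PMAIP1, CDKN1A, PLK3 and TP53I3, and lower in 2, POLH and XPC (camera adjusted p = 0.26; 3 higher and 1 lower adjusted over the list alone). CDKN1A, an inhibitor of cell cycle kinases, went from 6.79 ± 1.94 to 20.6 ± 0.42 CPM. ATF4 and amino acid response genes were higher in 4 of 18, ATF3, SLC7A11, SLC3A2 and PSAT1, and lower in 1, SLC7A5 (camera adjusted p = 0.12, with the same counts adjusted over the list alone). The stress factor gene DDIT3 stood at 26.5 ± 5.28 and 34.1 ± 2.24 CPM (edgeR adjusted p = 0.11), with 0.024 without DMSO replicate 3. ATF3 went from 5.86 ± 1.75 to 36.2 ± 1.98 CPM. Without DMSO replicate 3 the ATF4 list and the fatty acid list were called (camera adjusted p = 0.029 and 0.029), with adjusted p = 0.55 and 0.40 with an estimated correlation in those libraries. Unfolded protein response genes were higher in 5 of 20 and lower in 3, SYVN1, CALR and EDEM1 (camera adjusted p = 0.49, with the same counts adjusted over the list alone; the median was slightly below 0 and the test pointed up), and SYVN1 had a log2 fold change of -1.75. Heat shock genes were higher in 5 of 15 and lower in 2, HSPA8 and HSP90AB1 (camera adjusted p = 0.37; 6 higher and 3 lower adjusted over the list alone). HSPB1 went from 0.73 ± 0.33 to 9.53 ± 1.01 CPM. Ferroptosis and iron genes were higher in 5 of 16 and lower in 1, DHODH (camera adjusted p = 0.14, with the same counts adjusted over the list alone). Splicing stress and decay-sensitive genes were higher in 6 of 22 and lower in 5 (camera adjusted p = 0.34; 7 higher and 5 lower adjusted over the list alone). GADD45B went from 45.3 ± 4.50 to 203 ± 6.22 CPM. Several of these counts moved by over 1.5 times when a library was left out. Cell death genes were higher in 7 and lower in 5 without DMSO replicate 2, and higher in 4 and lower in 1 without treated replicate 1, 2 or 3. p53 targets were higher in 6 and lower in 4 without DMSO replicate 2, higher in 4 and lower in 1 without treated replicate 1, and higher in 3 and lower in 1 without DMSO replicate 1 or treated replicate 2 or 3. Unfolded protein response genes were higher in 6 and lower in 5 without DMSO replicate 2, higher in 8 and lower in 2 without DMSO replicate 3, and higher in 3 and lower in 2 without treated replicate 2 or 3. Heat shock genes were higher in 3 and lower in 3 without DMSO replicate 1, and higher in 3 and lower in 1 without treated replicate 1, 2 or 3. Ferroptosis genes were higher in 8 and lower in 1 without DMSO replicate 2, and higher in 6 and lower in 2 without DMSO replicate 3. With the length and GC trend removed, chosen after seeing the data, the p53 list had 7 higher and 3 lower genes, the ATF4 list 5 and 3, the unfolded protein list 4 and 5, the heat shock list 6 and 4, and the ferroptosis list 5 and 2.

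The remaining lists were not called at the preset correlation either. In fry, adjusted p was 0.0039 for interferon-stimulated and 0.046 for T cell genes, both up. It was 0.74 for glycolysis and hypoxia and 0.58 for FOXO genes. Interferon-stimulated genes were higher in 10 of 26 and lower in 3, OAS2, IFI44L and XAF1 (camera adjusted p = 0.21; 10 higher and 4 lower adjusted over the list alone). IRF7 went from 15.5 ± 4.66 to 72.9 ± 4.21 CPM. Glycolysis and hypoxia genes split 7 higher and 7 lower of 28 (camera adjusted p = 0.70; 8 higher and 7 lower adjusted over the list alone). That split was 9 higher and 12 lower without DMSO replicate 2, 4 and 5 without treated replicate 2, 3 and 5 without treated replicate 3, and 12 and 6 with the length and GC trend removed, an alternative chosen after seeing the data. PFKFB4 went from 6.37 ± 0.82 to 1.67 ± 0.37 CPM. FOXO targets and PI3K feedback genes were higher in 4 of 18 and lower in 5 (camera adjusted p = 0.79, with the same counts adjusted over the list alone). TXNIP went from 99.3 ± 8.60 to 252 ± 7.71 CPM. Among markers of other cell types, 7 T cell genes were tested, of which LCK, TRBC2 and CD247 were higher and IL7R lower (camera adjusted p = 0.26, with the same counts adjusted over the list alone), LCK at 0.74 ± 0.25 and 2.62 ± 0.32 CPM. Among the untested T cell markers, CD3D, CD8A, CD4 and CD5 had 2, 3, 4 and 20 counts over the 6 libraries, and 4 were listed at 0. Of 3 tested myeloid genes 1, VCAN, was lower at 0.42 ± 0.07 and 0.11 ± 0.03 CPM. Of 3 fibroblast genes COL1A1 and FN1 were higher and VIM lower. COL1A1 had 0 counts over the DMSO libraries and 55 over the treated ones, at least 22.1-fold higher against a floor of 3 counts over the group. Of epithelial markers 1 was tested, without passing, and of erythroid markers 0. The untested keratin genes KRT5, KRT8 and KRT14 had 30, 18 and 12 counts in treated replicate 3 and at most 6 in any other library. The myeloid, fibroblast, epithelial and erythroid lists, replication-dependent histones and mitochondrially encoded genes had too few tested members for the list test. On log2(TPM + 1), a scale set by more than the listed genes, limma-trend did not call PTTG1, FTL, RPL27, RPS27, VCAN or ABCG1 (adjusted p of 0.11, 0.054, 0.051, 0.055, 0.49 and 0.26), each with its direction kept. Without treated replicate 1, 2 or 3 interferon-stimulated genes were higher in 8 and lower in 1, and FOXO targets higher in 2 and lower in 4. With the trend removed, interferon-stimulated genes were higher in 11 and lower in 7. T cell genes were higher in 5 and lower in 1 without DMSO replicate 3, and 2 myeloid genes were lower without DMSO replicate 3 or treated replicate 1. Fibroblast genes were higher in 1 without DMSO replicate 1 or 3 or any treated library, and lower in 0 without treated replicate 1.

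**Figure D3:**
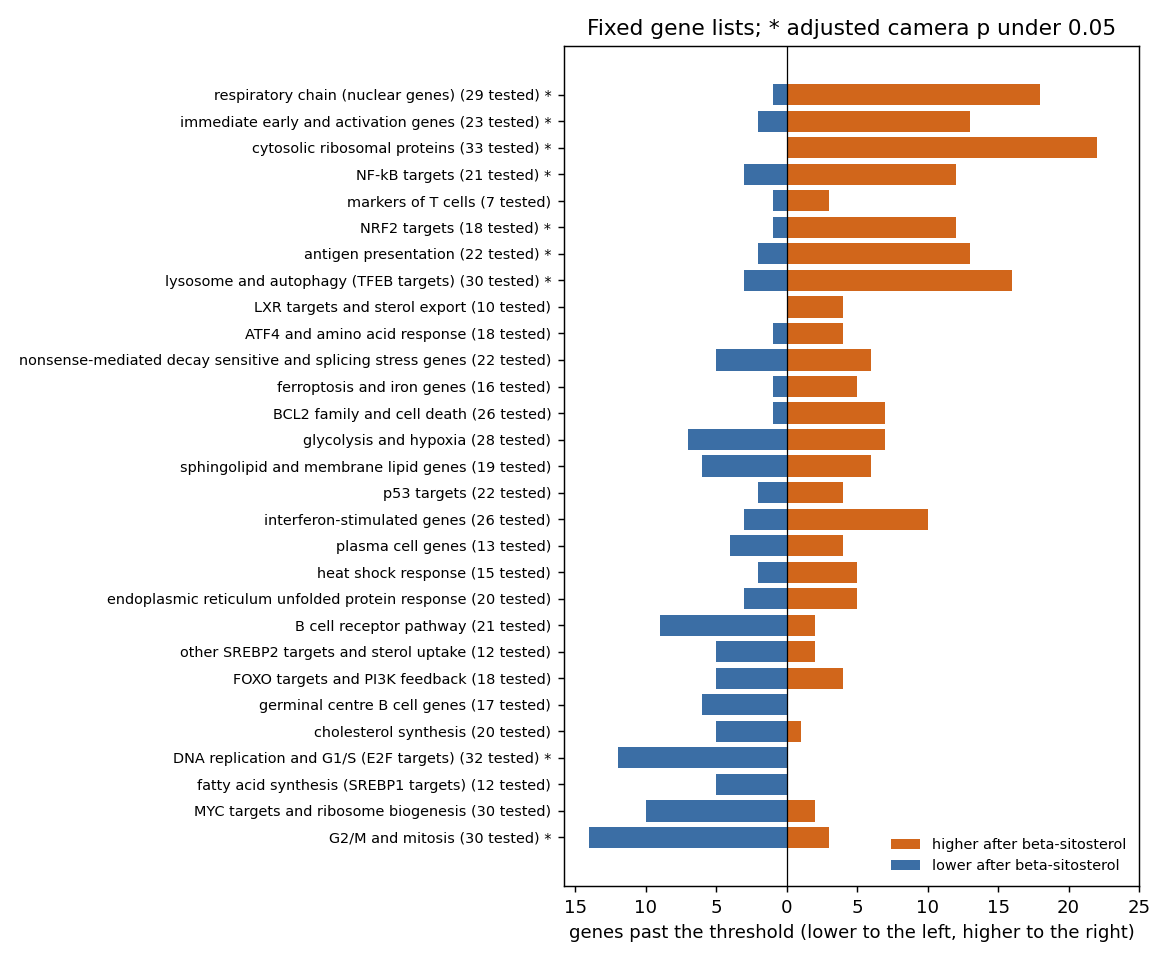
Number of genes past the threshold in each tested list, lower to the left in blue and higher to the right in orange, with the tested number beside each name and an asterisk where the adjusted camera p at the preset correlation was under 0.05. Cytosolic ribosomal proteins show 22 higher and 0 lower genes, and G2/M genes 3 higher and 14 lower.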

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

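Direction was kept in every call shared between the main analysis and each alternative chosen before the data were examined. Log2(TPM + 1) called 2939 genes, 713 higher, log2(TPM + 0.1) called 2935, 691 higher, and log2(TPM + 1) without a filter 2242, 613 higher and 1629 lower; the cause was not tested. The last of these did not call 13 of the named genes called in the main analysis. A 2-fold minimum left 1782, 1048 higher and 734 lower, by its construction. Leaving out each library gave 3094 to 6640 calls, 1593 to 3549 of them lower, the fewest without treated replicate 2 and the most without DMSO replicate 2. With the length and GC trend removed, an alternative chosen after seeing the data, 5764 genes were called, and with DMSO replicate 2 also left out 7549, 3397 higher and 4152 lower; 1 and 7 of the calls shared with the main analysis then had the opposite direction. Of the gene lists, 0 were called with an estimated correlation and 21 with fry, which asks another question. Same-numbered samples deviated together with correlations across genes of 0.04, 0.10 and 0.15, too low to treat the numbers as pairs, though each sample correlated best with its own number, a hint from the data and not from the design; a replicate block gave 4743 calls and 9 lists.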

Other observations

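The gene families, the length, span and GC tests, the trend removal, the test without DMSO replicate 2 and the small RNA test below were chosen after the main results were seen. Families of symbols with at least 20 tested members, 52 in all, were examined by camera at the preset correlation, and 8 were called. Of 26 HLA genes 18 were higher and 0 lower (median log2 fold change 0.88, or 0.63 with the length and GC trend removed, limma camera adjusted p = 3.66e-05), and of 48 mitochondrial ribosomal MRPL genes 19 were higher and 1 lower (median 0.37, or 0.15 with the trend removed, adjusted p = 5.97e-04). TRIM genes, many of them ubiquitin ligases, were lower in 19 of 43 and higher in 2 (median -0.49, or -0.46 with the trend removed, adjusted p = 8.98e-04), and kinesin KIF genes lower in 12 of 28 and higher in 0 (median -0.41, or -0.38 with the trend removed, adjusted p = 0.0036). None of the 8 held with an estimated correlation, where adjusted p ran from 0.49 for TRIM to 0.78 for COX genes.

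Only 1 of the 10 splits of the 6 samples into 3 and 3, the real one, gave 4697 genes, and the highest of the other splits gave 0 at the adjusted threshold with edgeR and 208 at an unadjusted p under 0.05. All other splits mix treated and DMSO libraries within a group. Any difference between treated and DMSO libraries then adds to the spread within groups, so low gene counts there are partly built in. For gene lists 1 of the 10 splits, the real one, called 9, and the highest other called 7. With 10 splits the share cannot fall under 0.05. That number came from each of the 3 splits that grouped DMSO replicates 1 and 2 with a treated library.

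Transcripts longer by the ratio of counts to TPM were lower after treatment. The median log2 fold change was 0.27 in the shortest eighth of genes and -0.31 in the longest. Across genes, which are not independent replicates, the partial Spearman correlation of the fold change with genomic span, given transcript length and level, was -0.20 (95% bootstrap interval -0.22 to -0.18), beyond the -0.1 set before it was computed, and -0.26 (-0.28 to -0.25) given GC content as well. With transcript length, given span, it was -0.069 (-0.088 to -0.050), or -0.048 (-0.067 to -0.030) given GC content as well, which leaves that trend undecided. DMSO libraries differed from one another as strongly in span and GC content. Plain Spearman correlations with span were 0.32, -0.30 and -0.40 for replicate 2 against 1, 3 against 1 and 3 against 2. Those with GC content were -0.32, 0.73 and 0.62, beside -0.28 (span) and -0.08 (GC content) for treatment. With transcript length, treatment stood at -0.23, beyond the 0.19, -0.08 and -0.19 of these DMSO pairs. Among treated pairs, span gave 0.07, -0.07 and -0.14, and length 0.010, 0.0002 and -0.005. Each pair sets 1 library against 1, and the treatment value sets 3 against 3. The trend may follow the span to be transcribed more than the length behind the TPM values, which need not be that of the mature RNA. Whether treatment or library preparation set the trend stays open.

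Ribosomal protein and respiratory chain genes had a median log2 fold change of 0.94 over 62 members (0.70 to 1.08). With the length and GC trend removed the median was 0.84 (0.70 to 0.98), and without DMSO replicate 2 it was 0.79 (0.50 to 0.90). The ranges in brackets are bootstrap intervals over genes and do not hold the spread between libraries. These medians argue against the length and GC trend as fitted, or that library alone, as the whole cause. The fitted length is that behind the TPM values, so these medians do not speak to a trend with mature RNA length. The trend with genomic span was not removed. Whether either trend raised these genes stays open. Whether correlation among these genes accounts for the list calls, which were lost with an estimated correlation, stays open. An effect of beta-sitosterol on these genes is a hypothesis that may be followed up with further DMSO cultures.

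Several short structured RNAs that are no product of introns rose from near 0, including SNORD3A, RMRP, RPPH1, RNU12, RNU5A-1 and copies of U6 and 5.8S RNA. More carry-over of all short RNA without a poly(A) tail is a candidate explanation, and over the 53 tested genes of these classes the median log2 fold change was 0.018 (-0.31 to 0.64), with 16 higher and 5 lower. The lower genes were the small nucleolar RNAs SNORD17, SNORA73B, SNORA71C, SNORD94 and SNORD62B. Other small nucleolar RNAs, SNORA60 and SNORA14B among them, were higher (log2 fold changes 2.46 and 1.53). These explanations cannot be told apart here, since reads from host gene introns can be counted for small nucleolar RNAs and library selection is not given. No biological explanation was tested.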
